A study of Mus musculus with 17 samples.

How the data were processed

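The deposited values come from 17 Illumina bead arrays that hold 46237 probes each. Per the submitters' processing notes, the arrays carried biotin-labelled total RNA and were processed with GenomeStudio, whose version is not given in the sources used here. The deposited non-normalized intensity of each probe and array is on a linear scale, and the values show no normalization between arrays. The detection p-value beside each intensity, per the file headers, states whether the probe lies above background, and how it was computed is not given in the sources used here. These p-values do not follow the order of the intensities, as 3401 to 7393 probes per array with detection were dimmer than the brightest probe without. They are therefore no ranks among control probes, and the background estimates, the percentages detected and every "at least" fold rest on them as deposited. The authors also deposited a normalized intensity on the linear scale, by a method that is not given, and it was used as an alternative only. Per the labels the control diet is a low-fat diet, and the submitters' protocol describes chow with 6% fat.

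Background was estimated from the intensities and detection p-values of each array (neqc of limma, offset 16), and the arrays were quantile normalized and put on the log2 scale. The estimated background had means of 93.7 to 100.5 and SDs of 3.46 to 4.09. A gene symbol was held by 35784 probes, 1 symbol each, for 22491 different symbols, and 10453 probes had none. By Entrez ID, 28620 probes matched the annotation table, which served for names only. Probes with a detection p below 0.05 on at least 2 arrays were kept, 25594 of them with a symbol, and the probe with the highest mean stood for its gene, which left 17166 genes. An "at least" fold is given where the probe that stands for the gene had detection on no array of 1 group, and it sets the mean of the other group against the higher of each value and the lowest detected value of its array (log2 4.33 to 4.42). Of 37 named results of genes with several probes, 32 had the same sign on every probe. The others were Itgad for the diet in Cpa3+/+ (lowest -0.14, highest 5.46) and in Cpa3Cre/+ (-0.02 and 5.96), Acsm3 for the diet in Cpa3+/+ (-2.48 and 0.37) and for KitW/Wv against Cpa3+/+ on HFD (-0.64 and 2.92), and Cma2 for the last comparison (-5.32 and 0.20). The 32 include results in which 1 probe hardly changed. Examples are Acsm3 for the diet in Cpa3Cre/+ (-3.64 and -0.04) and Cma2 for KitW/Wv against Cpa3+/+ on LFD (-4.68 and -0.25). Itgad on HFD had -5.23 and -0.02 for KitW/Wv against Cpa3+/+, and -5.61 and -0.08 against Cpa3Cre/+.

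A linear model with 1 mean for each of the 6 groups was fitted to all 17 arrays with limma 3.58.1 in R 4.3.3 (11 residual and 3.34 prior degrees of freedom). It gave 9 comparisons of 2 groups and 3 interactions of diet and genotype, with moderated p-values adjusted by Benjamini-Hochberg over all genes and a threshold of 0.05. Gene lists were written before the data were examined and held 484 genes, of which 442 were on the array and 405 were measured. Of the 28 lists, 27 were tested with camera at a preset correlation of 0.01, and again with a correlation estimated from the data. The eosinophil list had 3 measured members, under the minimum of 5, and was not tested as a list. Members were also adjusted over their list alone. The genes named by size are the 10 largest rises and the 10 largest falls past the threshold of a comparison (5 and 5 for an interaction), with the 3 smallest p where fewer than 3 passed, and symbols that are only clone or model numbers left out. In comparisons of 2 groups they were taken only from genes whose arrays did not overlap between the groups. The largest changes given in the results are those of such genes. List members were named without this condition. Of each list, up to 4 members past the threshold are named by size. Normalization, filter, model, threshold, lists and all alternatives but 1 were fixed before the data were examined.

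The pipeline was tried on simulated changes of 1.5-fold, 2-fold and 4-fold placed on 67, 67 and 66 of the 17166 genes. For the diet in Cpa3Cre/+ it recovered 10.4% of genes changed 1.5-fold, 46.3% of those changed 2-fold and 87.9% of those changed 4-fold, with 4% of calls false. The values were 1.5%, 26.9%, 86.4% and 3.8% for the diet in Cpa3+/+, 13.4%, 46.3%, 84.8% and 5.9% in KitW/Wv, and 3%, 16.4%, 71.2% and 1.6% for the interaction of KitW/Wv and Cpa3+/+. Each gene was drawn independently from a normal distribution with its own mean and residual SD, in a single draw per comparison. Correlation between genes, arrays that stand apart and larger numbers of changed genes were not simulated, so the rates may differ in these data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.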

Results

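Gene expression in mouse epididymal adipose tissue was measured on 17 Illumina bead arrays of total RNA. The mice were of the WBB6F1 background and of 3 genotypes. Cpa3+/+ mice were the wild type. Cpa3Cre/+ mice carry a Cre knock-in at the mast cell protease gene Cpa3 and lack mast cells. KitW/Wv mice carry 2 mutant alleles of the receptor tyrosine kinase gene Kit, which lowers Kit signalling in mast cells and other blood-forming cells. Each genotype was fed either a high-fat diet (HFD, 60% of energy from fat) or a low-fat diet (LFD, 6% fat) for 12 weeks, and tissue was taken after a 5 h fast. The HFD groups held 2 Cpa3+/+, 3 Cpa3Cre/+ and 3 KitW/Wv arrays, and each LFD group held 3. The median deposited intensity per array lay between 98.6 and 107.4, over a mean background of 93.7 to 100.5, and 46.9% to 51.7% of the probes of an array were detected. After normalization, arrays of the same group correlated with r between 0.94 and 0.99 across the 17166 genes (16 pairs). The labels number the samples but do not say that each is a separate animal, so the p-values measure the spread between these samples. The small number of arrays limits the precision of every estimate.

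On the first principal component, which held 26.7% of the variance, the 5 Cpa3+/+ and Cpa3Cre/+ arrays on HFD lay between -59.3 and -29.6. The other 12 arrays, KitW/Wv on HFD included, lay between 1.3 and 29.3. Some arrays stood apart from their groups in markers of other tissues or cells, given here as the mean log2 deviation of each list from its average over all arrays. Cpa3+/+ LFD array 3 had epididymis and testis markers at 3.18. KitW/Wv HFD array 1 had B cell markers at 2.20, skeletal muscle markers at 2.07 and T and NK cell markers at 1.21. Cpa3Cre/+ LFD array 2 had mesothelial and epithelial markers at 1.10 and muscle markers at 1.09. KitW/Wv LFD array 3 had B cell markers at 1.21. Red blood cell markers reached 1.54 in KitW/Wv HFD array 3, 1.13 in KitW/Wv LFD array 2 and 1.02 in KitW/Wv LFD array 3.

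The targeted genes were examined first. Cpa3 was high in all 5 Cpa3+/+ arrays, at log2 intensities of 7.32 to 8.54, and near background in the 12 arrays of the other genotypes, at 4.09 to 5.21. The Cpa3 probe used was detected on 1 of 3 Cpa3Cre/+ HFD arrays and on none of the other 9 Cpa3Cre/+ or KitW/Wv arrays. All 3 probes of Cpa3 were lower in these genotypes than in Cpa3+/+, the weakest by 0.92 (HFD) and 0.79 (LFD) in Cpa3Cre/+ and by 0.92 and 0.86 in KitW/Wv on the log2 scale. Kit mRNA lay between 6.76 and 8.77 on all 17 arrays and passed the threshold in no comparison. The largest Kit difference was -0.89 in KitW/Wv against Cpa3+/+ on LFD (SE 0.32, limma adjusted p = 0.862). The positions of the probes relative to the altered alleles are not given in the sources used here, so the Kit level does not check the KitW/Wv label.

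Cpa3Cre/+ against Cpa3+/+ set mice that lack mast cells against the wild type. The knock-in also alters a copy of Cpa3 and adds Cre, which this comparison does not separate from the loss of mast cells. KitW/Wv, whose label names no knock-in, had equally low mast cell markers. Their mean deviation per array was -0.61 to -0.15 in Cpa3Cre/+, -0.49 to -0.31 in KitW/Wv and 0.78 to 1.27 in Cpa3+/+. As a list, these markers were thus also low without the knock-in. Of the genes past the threshold, 5 of 7 on HFD and 5 of 6 on LFD were mast cell protease genes. On HFD, 7 genes passed the threshold (limma, Benjamini-Hochberg adjusted p below 0.05) and all 7 were lower in Cpa3Cre/+ (n = 3 against 2). By the probes used, the chymase genes Cma2 and Mcpt4 were not detected in any Cpa3Cre/+ array, and were at least 33.5-fold lower (adjusted p = 1.35e-08) and at least 17.2-fold lower (adjusted p = 7.96e-07). A second Cma2 probe changed by -0.13 on the log2 scale on HFD and by -0.24 on LFD. Cpa3 was 13.7-fold lower (log2 fold change -3.77, SE 0.26, adjusted p = 3.05e-06) and Cma1, another chymase, 11.4-fold lower (-3.51, SE 0.26, adjusted p = 3.87e-06), each detected on 1 of 3 Cpa3Cre/+ arrays. The tryptase gene Tpsb2 was at least 10.8-fold lower (adjusted p = 2.05e-06), and Fcer1a, the alpha chain of the high-affinity IgE receptor, at least 4.88-fold lower (adjusted p = 0.0032). The seventh gene was the odorant receptor gene Olfr1395, at least 1.89-fold lower (adjusted p = 0.0426). On LFD, 6 genes passed, all lower in Cpa3Cre/+ (n = 3 against 3). Cma2 was at least 21.3-fold lower, Cpa3 at least 10.3-fold lower (adjusted p = 2.81e-06), Mcpt4 at least 9.25-fold lower, Tpsb2, detected on 1 of 3 Cpa3Cre/+ arrays, 6.24-fold lower and Cma1 5.62-fold lower. S100a8, which encodes a calcium-binding protein abundant in neutrophils, was 5.12-fold lower (-2.36, SE 0.31, adjusted p = 0.0051). Of the 11 measured mast cell markers, 4 fell on HFD and 3 on LFD over all genes, and 6 fell on each diet when adjusted over the list alone. The list as a whole was lower, with a median of -1.11 on HFD and -0.71 on LFD (camera adjusted p = 3.29e-17 and 5.62e-20), and both calls held with an estimated correlation (adjusted p = 6.7e-05 and 3.19e-05). On LFD the neutrophil markers were also lower, with 1 of 11 members past the threshold, 3 when adjusted over the list alone, and a median of -0.32 (camera adjusted p = 9.31e-06, and 0.00785 with an estimated correlation). With 1 array left out in turn, Olfr1395 lost its call on HFD without any of the 5 arrays (adjusted p = 0.096 to 0.548) and Fcer1a without Cpa3+/+ HFD array 2 (adjusted p = 0.197). The other 5 genes on HFD and all 6 on LFD kept theirs. With only the groups compared in the fit, 2 of the 6 on LFD passed (Cma2 and Cpa3), and Mcpt4, Tpsb2, Cma1 and S100a8 did not.

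**Figure D1:**
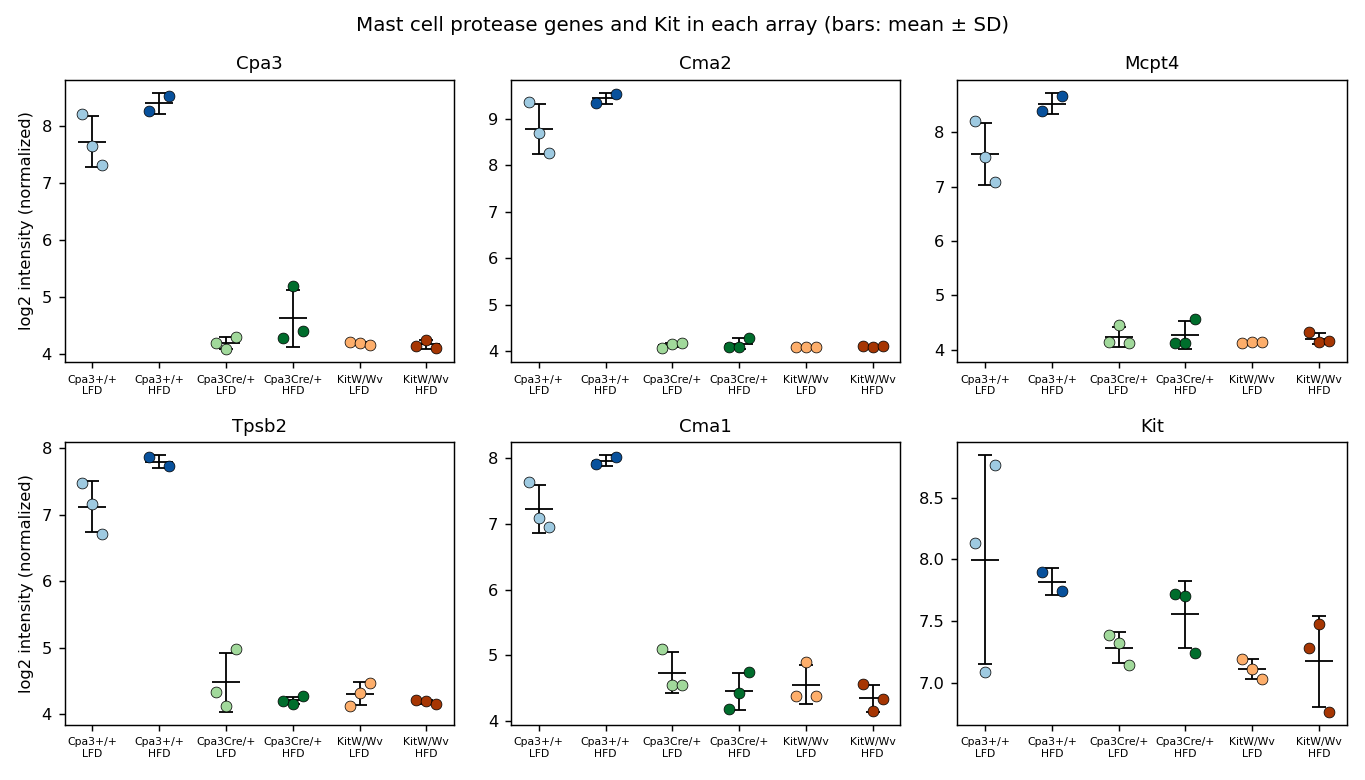
Normalized log2 intensity (vertical axes) of 5 mast cell protease genes and Kit on each array, by genotype and diet (horizontal axes), with the group mean and SD as bars. The protease genes are high in the 5 Cpa3+/+ arrays, with Cpa3 at 7.32 to 8.54, and near background in the 12 others, while Kit lies between 6.76 and 8.77 on all arrays.

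In Cpa3+/+ mice the high-fat diet raised genes of macrophages and cell division. In total 590 genes were higher and 208 lower on HFD (n = 2 against 3). The largest rise was in Tph2, which encodes the neuronal form of tryptophan hydroxylase, with a log2 fold change of 6.82 (SE 0.48, 113-fold, limma adjusted p = 4.24e-06). It was followed by the integrin gene Itgad (5.46, SE 0.43, detected on 1 of 3 LFD arrays), the gastric lipase gene Lipf (5.23, SE 0.46, detected on 2 of 3), the ubiquitin-like modifier gene Ubd (4.92, SE 0.43) and the proteoglycan gene Ncan, which was not detected on any LFD array and was at least 17.8-fold higher on HFD (adjusted p = 5.32e-07). The choline transporter gene Slc5a7 rose by 4.21 (SE 0.49) and was detected on 1 of 3 LFD arrays. Mmp12, the macrophage metalloelastase, rose by 4.10 (SE 0.51), Lctl by 3.98 (SE 0.80), the matrix gene Comp by 3.96 (SE 0.40) and Gpnmb, a glycoprotein of lipid-laden macrophages, by 3.83 (SE 0.43). Among the falls, the transcription factor gene Irf4 had a log2 fold change of -3.82 (SE 0.89, adjusted p = 0.0234). The angiotensinogen gene Agt followed at -2.91 (SE 0.34), the protease gene Prtn3 at -2.63 (SE 0.42), the adhesion receptor gene Adgrg2 at -2.59 (SE 0.60) and Acsm3, an acyl-CoA synthetase gene, at -2.48 (SE 0.59). Fam13a fell by 2.45, Vstm2b by 2.35, the phosphoenolpyruvate carboxykinase gene Pck1 by 2.33, Rgs2 by 2.32 and Ripk4 by 2.30 on the log2 scale, with adjusted p between 0.00124 and 0.0157.

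Of the 18 lipid-associated macrophage markers, 10 rose and 8 did not pass in Cpa3+/+, and 14 rose when adjusted over the list alone (median 1.44). Trem2 rose by 3.81 (SE 0.33) and the cathepsin gene Ctsk by 3.22 (SE 0.42). Of 18 general macrophage markers, 7 rose and 11 did not pass (13 rose adjusted over the list alone, median 0.84), with Cd68 at 2.61, Mpeg1 at 2.14 and Adgre1 at 1.73. Of 17 cell division genes, 9 rose and 8 did not pass (14 adjusted over the list alone, median 1.25), with the kinase gene Cdk1 at 2.60 and Birc5 at 2.17. These 3 lists passed the camera test (adjusted p = 4.87e-18, 2.11e-12 and 4.75e-16) and all 3 held with an estimated correlation (adjusted p = 0.00559 for each). Among 24 extracellular matrix genes 4 rose and 20 did not pass (12 rose adjusted over the list alone, median 0.88), led by Col5a2 at 1.51 and Lox at 1.22. In the cholesterol synthesis list, 4 of 17 rose, with Dhcr7 at 1.81 and Lss at 1.64 (8 adjusted over the list alone, median 0.79). Of the 10 MHC class II genes 3 rose (8 adjusted over the list alone), with H2-DMb1 at 2.15. Of 19 chemokines and inflammatory cytokines 5 rose (6 adjusted over the list alone), among them Il1rn at 2.72 and Ccl3, detected on 1 of 3 LFD arrays, at 1.16. The camera calls of these 4 lists (adjusted p = 3.87e-10, 3.34e-06, 6.16e-06 and 0.00218) were lost with an estimated correlation (adjusted p = 0.154, 0.0707, 0.2 and 0.157). Over the same contrast the epididymis and testis markers had a median of -0.87 (camera adjusted p = 0.0381, and 0.612 with an estimated correlation). Without Cpa3+/+ LFD array 3, in which these markers stood highest, the median was -0.02 (adjusted p = 0.915).

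The Cpa3+/+ comparison leaned on its 2 HFD arrays. It gave 229 genes without HFD array 1 and 243 without HFD array 2, where the remaining array was assumed to vary like the other groups. Of the 20 genes named above by size, 12 passed with each array left out in turn. Lctl, Irf4, Adgrg2, Acsm3, Vstm2b, Pck1 and Rgs2 lost their calls without HFD array 1 and without HFD array 2, Fam13a without HFD array 2, and Irf4, Acsm3, Rgs2 and Vstm2b also without LFD array 1, LFD array 2 or both. In these fits Lctl had log2 fold changes of 3.75 to 4.21, the falls -3.90 to -1.96, and adjusted p ran from 0.0513 to 0.253. Of 37 list members named by rule and past the threshold, 15 kept their call. They include Trem2, Mmp12, Gpnmb, Ctsk, Cd68, Mpeg1, Adgre1, Il1rn, Cdk1 and Birc5. With only the groups compared in the fit, Mpeg1 and Adgre1 did not pass. The other 22, among them Dhcr7, Lss, H2-DMb1, Ccl3, Col5a2 and Lox, lost theirs without HFD array 1, HFD array 2 or both, and some also without an LFD array.

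In Cpa3Cre/+ mice, which lack mast cells, the high-fat diet raised 1010 genes and lowered 552 (n = 3 against 3). How these divide depends on the scaling, since median scaling gave 1554 higher and 239 lower. The leading rises were again Tph2 (6.37, SE 0.43, limma adjusted p = 5e-07), Itgad (5.96, SE 0.39), Ubd (5.32, SE 0.39) and Mmp12 (4.83, SE 0.46). The lipid receptor gene of macrophages Trem2 rose by 4.74 (SE 0.30, adjusted p = 3.06e-07), Gpnmb by 4.47 (SE 0.39), the G protein regulator gene Rgs1 by 4.33 (SE 0.34), and Lipf and Vsig8 by 4.2 each. Slc5a7 was not detected on any LFD array and was at least 16.8-fold higher on HFD. The largest falls were in Acsm3 (-3.64, SE 0.53, adjusted p = 0.000375), Irf4 (-3.57, SE 0.80), the fatty acid oxidation gene Eci3 (-3.09, SE 0.31) and Fam13a (-3.03, SE 0.36). Cplx1 fell by 2.87, Ripk4 by 2.83, Pck1 by 2.83, Agt by 2.82, Mycl by 2.75 and the glutathione transferase gene Gsta4 by 2.59 on the log2 scale, with adjusted p between 1.84e-06 and 0.000768. Cplx1 was detected on 1 of 3 HFD arrays, and Tph2, Itgad, Lipf and Vsig8 on 2 of 3 LFD arrays.

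General macrophage markers rose in Cpa3Cre/+ in 15 of 18 cases (median 1.36), with Cd68 at 3.62, Mpeg1 at 2.75, Tyrobp at 2.71 and Adgre1 at 2.40. Lipid-associated macrophage markers rose in 14 of 18 (median 1.75), with Ctsk at 3.65, and cell division genes in 14 of 17 (median 1.48), with Mki67 at 2.59 and Prc1 at 2.40. Adjusted over the list alone, 15, 16 and 15 members of these lists rose. All 3 passed camera (adjusted p = 1.53e-20, 1.77e-20 and 1.56e-18) and held with an estimated correlation (adjusted p = 0.00169, 0.00258 and 0.00169). Of the 19 chemokines and inflammatory cytokines, 8 rose (9 adjusted over the list alone, median 0.93), among them Il1rn at 3.24, Ccl3 (detected on 1 of 3 LFD arrays) at 1.94 and Ccl9 at 1.81, and this list too held with an estimated correlation (adjusted p = 0.0391). Extracellular matrix genes rose in 14 of 24 (21 adjusted over the list alone, median 1.10), with Timp1 at 2.88, Col6a2 at 1.91 and Col1a1 at 1.86. In this list 22 of the 24 members had their highest value in Cpa3Cre/+ HFD array 2. MHC class II genes rose in 8 of 10 (8 adjusted over the list alone, median 1.41), with H2-DMb2 at 2.77, and 4 of 17 cholesterol synthesis genes (6 adjusted over the list alone, median 0.63), with Dhcr7 at 1.73. The camera calls of these 3 lists (adjusted p = 8.43e-15, 1.1e-10 and 4.66e-05) were lost with an estimated correlation (adjusted p = 0.0865, 0.0865 and 0.0958). Among the adipocyte markers, the leptin gene Lep rose by 1.89 and the resistin gene Retn fell by 1.49 on the log2 scale, and the list as a whole did not pass (2 of 17 rose, 2 fell, camera adjusted p = 0.495). Without Cpa3Cre/+ HFD array 2 the comparison gave 946 genes, and Irf4 lost its call without LFD array 3 (-3.09, adjusted p = 0.0537). The other 19 genes named by size passed with each array left out, as did 38 of the 55 list members named by rule, all those given in this paragraph among them. With only the groups compared in the fit, Col1a1, Col6a2 and Lep did not pass.

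In KitW/Wv mice 1 of 17166 genes passed the threshold between HFD and LFD by limma (n = 3 against 3). An unadjusted p below 0.05 was held by 583, fewer than expected by chance over all genes. The 1 gene past the threshold was Igh-4, an immunoglobulin heavy chain gene, which was 10.6-fold higher on HFD (log2 fold change 3.40, SE 0.44, adjusted p = 0.0298). Its call was lost without HFD array 1 (3.52), HFD array 3 (2.94), LFD array 1 (3.29) or LFD array 2 (3.09), with adjusted p of 0.0821 to 0.295. Next by p came Gpnmb (2.50, SE 0.39, adjusted p = 0.115) and the cell cycle inhibitor gene Cdkn2c (-1.05, SE 0.18, adjusted p = 0.269), neither past the threshold. No member of any of the 28 gene lists passed over all genes. The lipid-associated macrophage list had a median of 0.20 and 3 of its 18 members rose when adjusted over the list alone (camera adjusted p = 8.82e-05, and 0.31 with an estimated correlation). General macrophage markers had a median of 0.10 (camera adjusted p = 0.12) and cell division genes 0.02 (camera adjusted p = 0.257). Fatty acid synthesis genes had a median of -0.50 (camera adjusted p = 1.9e-10, and 0.16 with an estimated correlation), with Fasn at -1.53 (SE 0.53) and Elovl6 at -1.43 (SE 0.55), none past the threshold. The mean deviation of this list was -0.22, 0.53 and 0.43 on LFD arrays 1, 2 and 3, and -0.22, -0.53 and -0.29 on the HFD arrays. Of its 19 members, 9 stood highest in KitW/Wv LFD array 2. B cell and muscle markers, which stood highest in KitW/Wv HFD array 1, had medians of 0.60 and 0.83 (camera adjusted p = 0.000904 and 0.000509, and 0.42 for both with an estimated correlation).

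**Figure D2:**
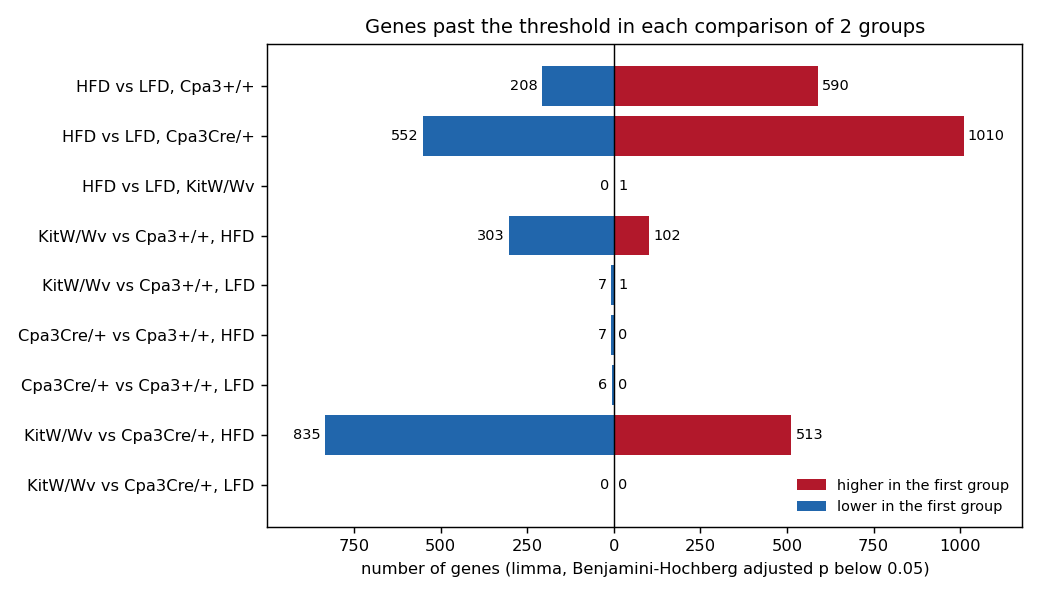
Number of genes past the limma threshold in each of the 9 comparisons of 2 groups (horizontal axis), with those higher in the first group to the right and those lower to the left. The diet changed 590 and 208 genes in Cpa3+/+, 1010 and 552 in Cpa3Cre/+, and 1 and 0 in KitW/Wv.

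The diet effects of the genotypes were then set against each other. Across the 17166 genes, which are not independent replicates, the log2 fold changes of Cpa3+/+ and Cpa3Cre/+ correlated with Pearson r = 0.682 (Spearman rho = 0.536). The 2 comparisons share no array. They had 480 genes called higher in both, where 34.7 would overlap by chance, and 146 called lower in both, against 6.7 by chance. The correlation was r = 0.1 (rho = 0.042) between Cpa3+/+ and KitW/Wv and r = 0.240 (rho = 0.146) between Cpa3Cre/+ and KitW/Wv. Both moved with single arrays, the first from 0.025 to 0.153 and the second from 0.088 to 0.309 with each array left out. Over the 798 genes called in Cpa3+/+, taken in the direction of that call, the median log2 fold change was 1.29 in Cpa3Cre/+ and 0.10 in KitW/Wv, and 98.4% and 66.5% of the genes had the same sign. Over the 1562 genes called in Cpa3Cre/+, the medians were 0.83 in Cpa3+/+ and 0.08 in KitW/Wv.

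**Figure D3:**
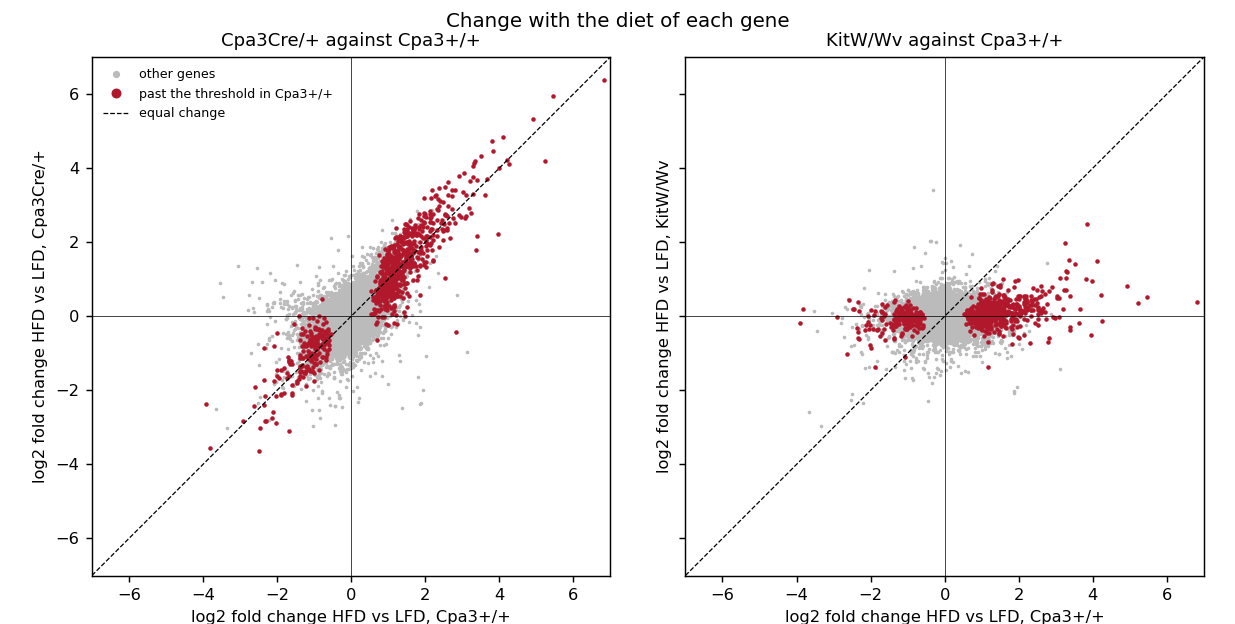
Log2 fold change of each gene between HFD and LFD in Cpa3+/+ (horizontal axes) against that in Cpa3Cre/+ (left) or KitW/Wv (right, vertical axes), with the 798 genes called in Cpa3+/+ in red. The red genes follow the line of equal change on the left (r = 0.682 over all genes) and lie near 0 on the vertical axis on the right (r = 0.1).

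The interaction of diet and genotype was tested for each gene. Against Cpa3+/+, 152 genes responded differently in KitW/Wv (15 with a higher and 137 with a lower response). The lower responses were led by Tph2 (-6.42, SE 0.64, limma adjusted p = 0.000402), Lipf (-4.86, SE 0.62) and Comp (-4.46, SE 0.54), with Itgad (adjusted p = 0.00124) and Ncan (adjusted p = 2.01e-05). The last 2 have no exact size, since Itgad was not detected on any KitW/Wv LFD array and Ncan on no LFD array of Cpa3+/+ or Cpa3Cre/+. The largest higher responses were in Igh-4 (3.73, SE 0.66, adjusted p = 0.0174), Agt (2.90, SE 0.46), Fam13a (2.65, SE 0.54), Ripk4 (2.45, SE 0.46) and Wdr92 (2.17, SE 0.47). Against Cpa3Cre/+, 436 genes differed (77 higher, 359 lower). Median scaling gave 48 higher and 476 lower. With each array left out, 303 to 474 genes passed, of which 34 to 119 were higher. Tph2 (-5.98, SE 0.61), Ubd (-4.51, SE 0.55) and Lipf (-3.83, SE 0.58), with Itgad and Ncan, led the lower responses. Acsm3 (3.84, SE 0.74), Igh-4 (3.30, SE 0.62), Fam13a (3.23, SE 0.51), Eci3 (3.22, SE 0.44) and Pck1 (3.21, SE 0.59) led the higher ones. Between Cpa3Cre/+ and Cpa3+/+ the limma interaction gave 0 genes. An unadjusted p below 0.05 was held by 686, fewer than expected by chance over all genes, and the smallest p belonged to Oxnad1 (-1.70, SE 0.29, adjusted p = 0.563). General macrophage markers responded less in KitW/Wv than in Cpa3+/+ (4 of 18 members lower, median -0.70) and than in Cpa3Cre/+ (9 of 18, median -1.36). The same held for lipid-associated macrophage markers (4 and 9 of 18, medians -1.23 and -1.45), cell division genes (4 and 7 of 17, medians -1.30 and -1.37) and cholesterol synthesis genes (2 and 3 of 17, medians -1.12 and -0.98). With an estimated correlation the adjusted p of these 4 lists was 0.0139, 0.0139, 0.0108 and 0.0202 against Cpa3+/+ and 0.00216, 0.00478, 0.00216 and 0.0348 against Cpa3Cre/+. Part of the difference from either genotype in general macrophage markers and cell division genes lay on LFD. For general macrophage markers the mean deviation per array there was -0.23 to -0.14 in KitW/Wv, -0.8 to -0.46 in Cpa3Cre/+ and -0.44 to -0.36 in Cpa3+/+. On HFD it was -0.19 to 0.13, 0.85 to 0.9 and 0.53 to 0.59. For cell division genes it was -0.3 to -0.21, -0.59 to -0.35 and -0.74 to -0.46 on LFD, and -0.35 to -0.06, 0.8 to 1.15 and 0.68 to 0.73 on HFD. In the lipid-associated macrophage and cholesterol synthesis lists the LFD arrays of the genotypes overlapped. Thermogenic adipocyte genes (1 of 14 members lower, median -0.58) and stromal progenitor markers (0 of 13, median -0.54) also had a lower response against Cpa3+/+ as lists (adjusted p = 0.0265 and 0.0428 with an estimated correlation). The test against Cpa3+/+ moved with single arrays. It gave 27 and 34 genes without Cpa3+/+ HFD arrays 1 and 2, 89 without Cpa3+/+ LFD array 1, 95 and 72 without KitW/Wv HFD arrays 2 and 3, and 98, 88 and 73 without KitW/Wv LFD arrays 1, 2 and 3. Its 5 lower responses named here passed with each array left out. Igh-4 lost its call without either Cpa3+/+ HFD array (3.45 to 4.01) and Agt without array 2 (2.58), with adjusted p of 0.063 to 0.112. Ripk4 (2.25 to 2.53) lost its call without either Cpa3+/+ HFD array, Cpa3+/+ LFD array 1 or KitW/Wv LFD array 3. Fam13a (2.19 to 3.12) did so without any of these 4, Cpa3+/+ LFD array 2, KitW/Wv HFD arrays 2 and 3, or KitW/Wv LFD array 1. Wdr92 (1.74 to 2.60) did so without any array of the comparison but Cpa3+/+ LFD array 3 (adjusted p of the 3 genes 0.0539 to 0.283). Against Cpa3Cre/+ all 10 passed with each array left out. Of the list members named by rule, 3 of 19 kept their calls against Cpa3+/+ (Mpeg1, Itgax and Otop1) and 22 of 31 against Cpa3Cre/+.

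KitW/Wv and Cpa3+/+ on HFD compared the tissue of mice with reduced Kit signalling with the wild type under fat feeding. Mast cell, macrophage, cell division and cholesterol synthesis genes were lower in KitW/Wv, and 8 of the 10 rises named by size were in immunoglobulin or B lineage genes (102 genes higher and 303 lower, n = 3 against 2). No list of immunoglobulin genes was tested. The largest falls were in Tph2 (-6.79, SE 0.48, limma adjusted p = 1.92e-06), Itgad (-5.23, SE 0.43) and Lipf (-4.34, SE 0.46). The probes used for Cma2, Mcpt4 and Cpa3 were not detected in KitW/Wv and were at least 33.7-fold (adjusted p = 1.17e-08), 18.1-fold (adjusted p = 4.3e-07) and 16.5-fold lower (adjusted p = 6.5e-07). A second Cma2 probe changed by 0.20. Ncan (-4.18, SE 0.24), Comp (-3.78, SE 0.40), Slc5a7 (-3.71, SE 0.49) and Ubd (-3.69, SE 0.43) followed. In KitW/Wv, Ncan was detected on 1 of 3 arrays and Itgad, Comp and Slc5a7 on 2 of 3. Several immunoglobulin kappa segments led the rises, namely Igkv1-110 (5.81, SE 1.29, adjusted p = 0.0294), Igkv6-23 (5.05, SE 1.00), Igkv9-124 (3.86, SE 0.59) and Igkv4-62 (3.83, SE 0.74), together with Igh-4 (3.88, SE 0.49, adjusted p = 0.000789). Igh-4 and Igkv9-124 were detected on 1 of 2 Cpa3+/+ arrays. The B lineage genes Fcmr (3.87, SE 0.86), Mzb1 (3.43, SE 0.78) and Cd79b (2.86, SE 0.66) were also higher, as were Acsm3 (2.92, SE 0.59) and Pck1 (2.82, SE 0.47). Of the 11 mast cell markers 6 fell (6 adjusted over the list alone, median -1.95, adjusted p = 0.000974 with an estimated correlation). Lipid-associated macrophage markers fell in 8 of 18 (12 adjusted over the list alone, median -0.97), with Trem2 at -2.49 and Ctsk at -2.48. General macrophage markers fell in 5 of 18 (7 adjusted over the list alone, median -0.52), with Adgre1 at -1.48. Cell division genes fell in 5 of 17 (12 adjusted over the list alone, median -0.91), with Cdk1 at -1.70, and cholesterol synthesis genes in 3 of 17 (14 adjusted over the list alone, median -0.96), with Dhcr7 at -1.88. These 4 lists held with an estimated correlation (adjusted p = 0.00939, 0.013, 0.00939 and 0.0107). Among the 9 B cell markers 3 rose (6 adjusted over the list alone, median 1.504, camera adjusted p = 1.65e-05, and 0.191 with an estimated correlation). Beside this, 7 of the 9 B cell markers, 8 of the 13 T and NK cell markers and 8 of the 11 muscle markers had their highest value in KitW/Wv HFD array 1.

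With single arrays left out, this comparison gave 63 genes without Cpa3+/+ HFD array 1, 81 without Cpa3+/+ HFD array 2 and 167 without KitW/Wv HFD array 3. The 10 falls named by size and Igh-4 passed in every such fit. Each of the other 9 rises, which include Acsm3 and Pck1, lost its call without Cpa3+/+ HFD array 1, and all of them but Igkv9-124 without array 2. Igkv1-110, Igkv6-23, Fcmr, Mzb1 and Cd79b did so also without KitW/Wv HFD array 1 and without array 3, and Acsm3 without array 3. Their log2 fold changes in these fits were 2.12 to 5.84 and their adjusted p 0.0561 to 0.326. Of 37 list members named by rule, Mcpt4, Cma1, Tpsb2, Trem2 and the proton channel gene Otop1 passed in every such fit. The other 32, Ctsk, Adgre1, Cdk1 and Dhcr7 among them, lost their calls without Cpa3+/+ HFD array 1 or array 2.

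KitW/Wv against Cpa3Cre/+ on HFD compared 2 genotypes that both lack mast cells. It gave the most genes of the comparisons between genotypes, 513 higher and 835 lower in KitW/Wv (n = 3 against 3). With median scaling it gave 263 higher and 1338 lower. The falls were led by Tph2 (-6.54, SE 0.43, limma adjusted p = 8.19e-07), Itgad (-5.61, SE 0.39), Ncan (-3.99, SE 0.21), Ubd (-3.95, SE 0.39) and Slc5a7 (-3.26, SE 0.44). The triglyceride metabolism gene Pnpla3 (-3.22, SE 0.47), Plxdc1 (-3.19, SE 0.53), the DNA repair gene Zranb3 (-3.18, SE 0.26), Trem2 (-3.16, SE 0.30) and Vsig8 (-3.09, SE 0.34) followed. Of the 10 rises named by size 7 were in immunoglobulin genes, with Igl-V1 at 6.14 (SE 0.95, adjusted p = 0.00106), Igkv6-23 at 5.21, Igkv1-110 at 4.95, Igk-C at 4.79, Igkv9-124 at 4.00, Igh-4 at 3.79 and Igkv4-62 at 3.65. The B cell chemokine gene Cxcl13 was at 4.64 (SE 1.07, adjusted p = 0.0159), Fcmr at 4.18 and Mzb1 at 3.73. In Cpa3Cre/+, Fcmr and Mzb1 were detected on 1 of 3 arrays and 5 of the 7 immunoglobulin genes on 2 of 3. Neither Cpa3 (adjusted p = 0.299) nor the list of mast cell markers (median 0.01, camera adjusted p = 0.766) passed. Lipid-associated macrophage markers were lower in 12 of 18 (15 adjusted over the list alone, median -1.38), with the integrin gene Itgax, not detected in KitW/Wv, at least 4.94-fold lower. General macrophage markers were lower in 8 of 18 (13 adjusted over the list alone, median -0.64), with Adgre1 at -2.19 and Cd68 at -2.08. Cell division genes were lower in 12 of 17 (15 adjusted over the list alone, median -1.16), with Birc5 at -1.94 and Mki67 at -1.83, and cholesterol synthesis genes in 7 of 17 (13 adjusted over the list alone, median -0.89), with Dhcr7 at -2.19 and Lss at -1.72. The 4 lists held with an estimated correlation (adjusted p = 0.00808, 0.00808, 0.00765 and 0.0225). Extracellular matrix genes were lower in 13 of 24 (19 adjusted over the list alone, median -1.03, camera adjusted p = 7.41e-14, and 0.117 with an estimated correlation), with Col1a1 at -1.78. MHC class II genes were lower in 4 of 10 (8 lower and 1 higher adjusted over the list alone, median -0.84, camera adjusted p = 0.00031, and 0.305 with an estimated correlation), with H2-DMb1 at -2.35. B cell markers were higher in 4 of 9 (6 higher and 1 lower adjusted over the list alone, median 1.502, camera adjusted p = 0.000371, and 0.305 with an estimated correlation), and 7 of the 9 stood highest in KitW/Wv HFD array 1. Without Cpa3Cre/+ HFD array 1, 828 genes passed, without Cpa3Cre/+ HFD array 2, 682, and without KitW/Wv HFD array 3, 718. Of the 20 genes named by size, 17 passed in each of these and the other single-array fits. Igkv1-110 (4.32 to 4.78) and Cxcl13 (3.68 to 4.59) lost their calls without Cpa3Cre/+ HFD array 1 or 2 or KitW/Wv HFD array 1 or 3, and Igk-C (4.33) without Cpa3Cre/+ HFD array 2 (adjusted p = 0.0527 to 0.0746 over the 3 genes). Of 67 list members named by rule, 32 passed in every such fit, all those given in this paragraph among them. With only the groups compared in the fit, Col1a1 did not pass.

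**Figure D4:**
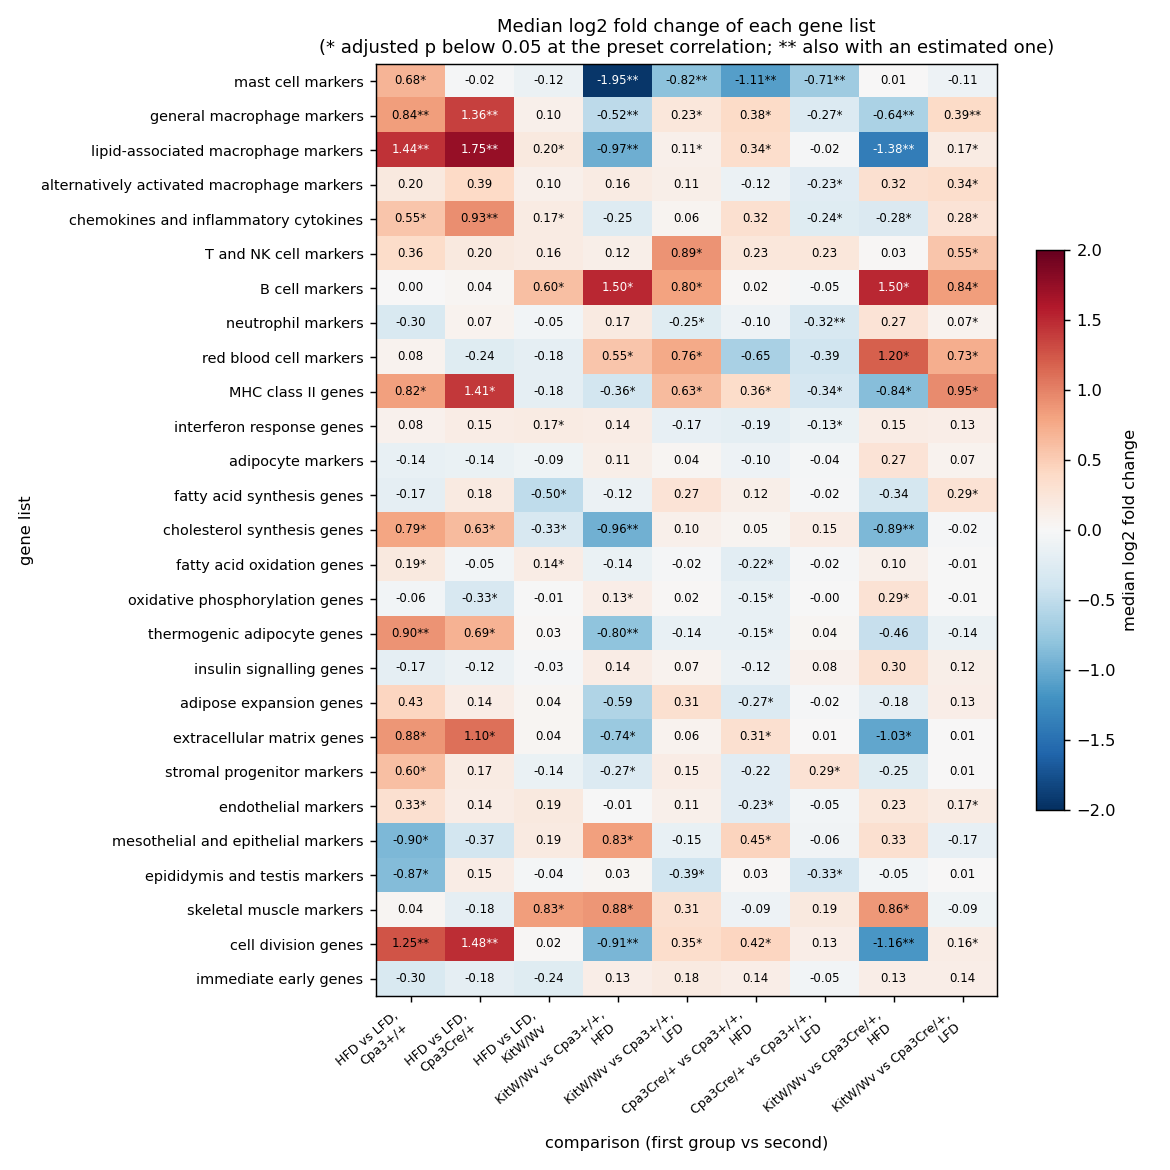
Median log2 fold change of each of the 27 gene lists tested (vertical axis) in each of the 9 comparisons (horizontal axis), in colour and as a number. The lipid-associated macrophage and cell division lists are high in the first 2 columns (1.44 and 1.75, 1.25 and 1.48), near 0 for the diet in KitW/Wv (0.20 and 0.02), and low in KitW/Wv against either genotype on HFD.

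On the low-fat diet KitW/Wv differed from the other genotypes in far fewer genes than on HFD. KitW/Wv against Cpa3+/+ gave 8 genes (n = 3 against 3), and mast cell proteases were again lower. Cma2 was at least 21.5-fold lower (limma adjusted p = 1.48e-08), Cpa3 at least 10.4-fold lower (adjusted p = 2.15e-06), Mcpt4 at least 9.57-fold lower, Tpsb2 at least 6.61-fold lower and Cma1, detected on 1 of 3 KitW/Wv arrays, 6.37-fold lower. Igkv9-124 was the 1 gene that was higher (4.05, SE 0.53, adjusted p = 0.00446). The phosphatase gene Dusp18 was at least 1.71-fold lower (adjusted p = 0.0351) and lost its call without any of the 6 arrays (adjusted p = 0.0923 to 0.207), and the eighth gene was the unnamed transcript A930008A22Rik (-1.51, SE 0.19, adjusted p = 0.00446). With only the groups compared in the fit, the 5 proteases passed and the other 3 genes did not. Of 11 mast cell markers 3 fell (6 adjusted over the list alone, median -0.82, adjusted p = 0.000161 with an estimated correlation). B cell markers had a median of 0.80 with no member past the threshold over all genes and 2 adjusted over the list alone (camera adjusted p = 1.38e-05, and 0.191 with an estimated correlation). Their mean deviation was -0.1, 0.4 and 1.21 on KitW/Wv LFD arrays 1, 2 and 3, so array 3 stood apart, and -0.58 to -0.33 on the Cpa3+/+ LFD arrays. Between KitW/Wv and Cpa3Cre/+ on LFD, 0 genes passed by limma and 773 had an unadjusted p below 0.05, fewer than expected by chance. The smallest p values belonged to Igkv9-124 (3.37, SE 0.53, adjusted p = 0.25), Igkv4-86 (2.11, SE 0.37, adjusted p = 0.318) and the MHC class II gene H2-Eb1 (0.91, SE 0.16, adjusted p = 0.318), none past the threshold. As a list, the general macrophage markers were higher in KitW/Wv (median 0.39, none of 18 past the threshold over all genes, 5 adjusted over the list alone, camera adjusted p = 1.99e-13, and 0.0115 with an estimated correlation). MHC class II genes had a median of 0.95 (none of 10 past the threshold, 8 adjusted over the list alone, camera adjusted p = 2.43e-17, and 0.0542 with an estimated correlation). On the same arrays the mean deviation of B cell markers was -0.1 to 1.21 in KitW/Wv and -0.67 to -0.59 in Cpa3Cre/+. For red blood cell markers it was 0.29 to 1.13 and -0.88 to -0.26.

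**Figure D5:**
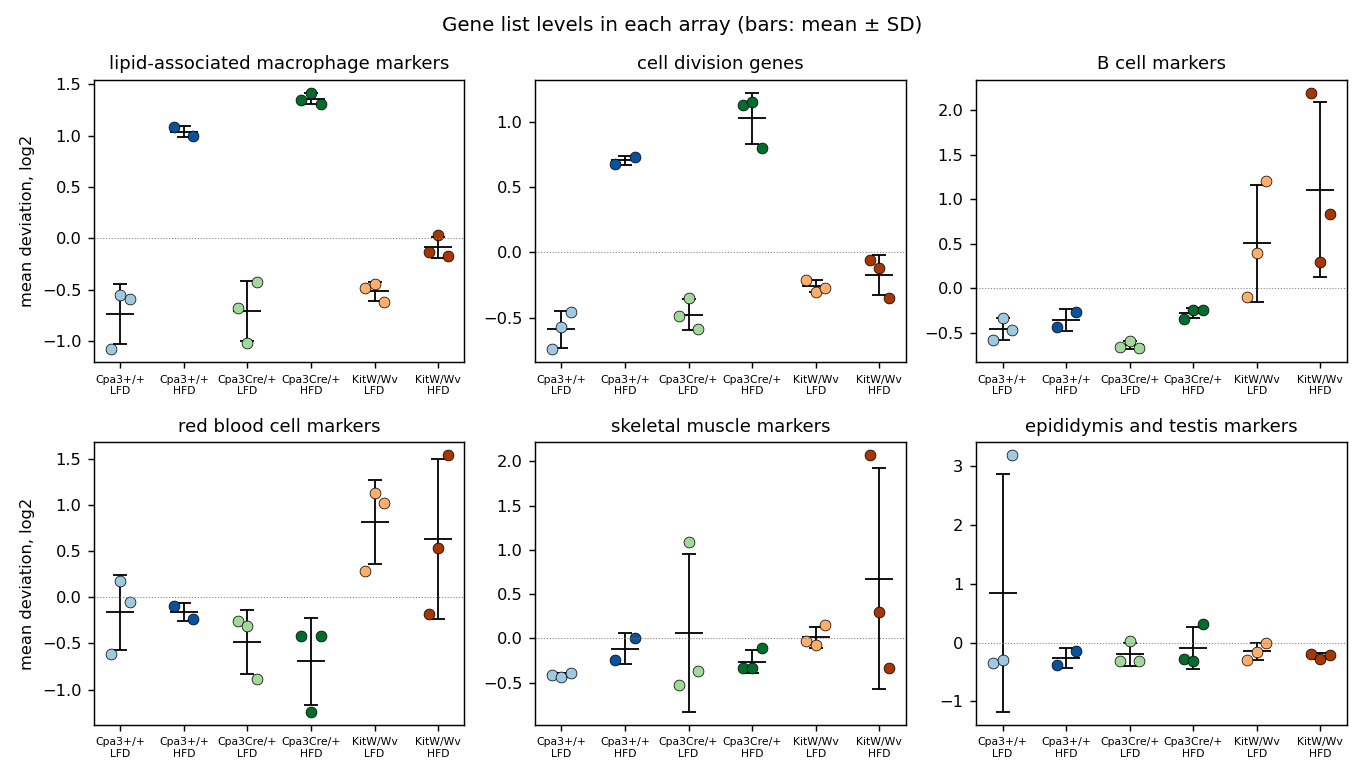
Level of 6 gene lists on each array (vertical axes, mean log2 deviation of the members from their average over the 17 arrays) by genotype and diet (horizontal axes), with the group mean and SD as bars. Lipid-associated macrophage markers reach 1.00 or more in the 5 Cpa3+/+ and Cpa3Cre/+ HFD arrays and at most 0.03 elsewhere, B cell markers reach 2.20 in KitW/Wv HFD array 1, and epididymis and testis markers 3.18 in Cpa3+/+ LFD array 3.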

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

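The tests of spread and of unnamed probes in this part were chosen after the results were seen.

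The response to the diet differed between genotypes in 152 genes for KitW/Wv against Cpa3+/+ and in 436 for KitW/Wv against Cpa3Cre/+. Against Cpa3+/+ the response was higher in KitW/Wv for Igh-4 (3.73), Agt (2.90), Fam13a (2.65), Ripk4 (2.45) and Wdr92 (2.17), and lower for Tph2 (-6.42), Itgad (-4.93), Lipf (-4.86), Comp (-4.46) and Ncan (-4.38). Against Cpa3Cre/+ it was higher for Acsm3 (3.84), Igh-4 (3.30), Fam13a (3.23), Eci3 (3.22) and Pck1 (3.21), and lower for Tph2 (-5.98), Itgad (-5.43), Ubd (-4.51), Ncan (-4.22) and Lipf (-3.83). The values of Itgad and Ncan are fitted and have no exact size, as Itgad was not detected on any KitW/Wv LFD array and Ncan on no LFD array of the other genotypes. Lists with a lower response in KitW/Wv than in Cpa3+/+ were general macrophage (-0.70), lipid-associated macrophage (-1.23), cholesterol synthesis (-1.12), thermogenic adipocyte (-0.58), stromal progenitor (-0.54) and cell division genes (-1.30). Against Cpa3Cre/+ they were general macrophage (-1.36), lipid-associated macrophage (-1.45), cholesterol synthesis (-0.98) and cell division genes (-1.37).

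The small diet effect in KitW/Wv could come from a larger spread between its arrays, from 1 deviating array, or from arrays exchanged between the diets. Spread is excluded, because the median change of the genes called in Cpa3+/+ was 0.098 in KitW/Wv (upper quartile 0.261) against 1.29 in Cpa3Cre/+, and the median residual SD was 0.235 in KitW/Wv against 0.271 in Cpa3Cre/+. A single array is excluded, because that median reached at most 0.133 with any KitW/Wv array left out. For an exchange, a diet score was built from the genes called in both other genotypes and scaled between the means of their LFD and HFD arrays. The 0.912 to 1.11 of their HFD arrays is thus set by construction. KitW/Wv arrays lay at 0.126 to 0.180 on LFD and at 0.172 to 0.318 on HFD. An exchange of arrays with a response as large as in the other genotypes is therefore excluded. An exchange of arrays with a small response is not, since the score does not separate the diets within KitW/Wv. Reduced Kit signalling itself and a lower body weight remain open and were not tested.

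Regrouping the arrays asked whether the 436 genes of the interaction with Cpa3Cre/+ might arise by chance. Of 100 splits of the same arrays 5, the real one included, gave as many genes, and the highest other split gave 840. The 4 others were all among the 9 drawn that keep the HFD arrays as labelled. Those splits keep the labelled difference between the genotypes on HFD, so they are not free of it and the count does not decide about chance.

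Probes without a gene symbol were tested apart, 5896 of them with detection on 2 arrays. Past the limma threshold were 66 for the diet in Cpa3+/+, 142 in Cpa3Cre/+ and 1 in KitW/Wv. Between genotypes there were 87 for KitW/Wv against Cpa3+/+ on HFD and 8 on LFD, 199 for KitW/Wv against Cpa3Cre/+ on HFD and 1 on LFD, and 4 and 31 for the interactions of KitW/Wv with Cpa3+/+ and with Cpa3Cre/+.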

How the results depend on the processing

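The fit without the 4 arrays that stand apart was chosen after the results were seen, and all other alternatives before. The 4 are Cpa3+/+ LFD array 3, KitW/Wv HFD array 1, Cpa3Cre/+ LFD array 2 and KitW/Wv LFD array 3. KitW/Wv HFD array 3 and LFD array 2, high in red blood cell markers, stayed in.

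Counts of genes moved over 1.5-fold as follows, and the cause was not tested. With only the groups compared in the fit, the diet gave 127 genes in Cpa3+/+, 767 in Cpa3Cre/+ and 0 in KitW/Wv, and Cpa3Cre/+ against Cpa3+/+ on LFD gave 2. The diet in KitW/Wv gave 2 with median scaling or array weights, 0 without a detection filter or with the authors' values, and 3 without the 4 arrays. Array weights gave 1454 for KitW/Wv against Cpa3+/+ and 3034 against Cpa3Cre/+ on HFD, 52 for Cpa3Cre/+ against Cpa3+/+ on HFD, and 268 and 797 for the interactions of KitW/Wv with Cpa3+/+ and Cpa3Cre/+. The interaction with Cpa3+/+ gave 89 with median scaling and 96 with a replicate block. Median scaling moved the median log2 fold change of all genes from -0.023 to 0.091 for the diet in Cpa3Cre/+, from 0.017 to 0.122 for Cpa3Cre/+ against Cpa3+/+ on HFD and from -0.004 to 0.106 for their interaction with the diet. Labels with the same number did not clearly pair. After removal of the group means, 16 of 40 such pairs had r over 0.1. Their median r was 0.072, against -0.035 for different numbers, and 7 of 17 arrays correlated best with their own number. With each array left out, counts ran from 229 to 861 (diet in Cpa3+/+), 946 to 1415 (diet in Cpa3Cre/+), 0 to 2 (diet in KitW/Wv), 63 to 306 and 682 to 1212 (KitW/Wv against Cpa3+/+ and Cpa3Cre/+ on HFD), and 27 to 194 (interaction with Cpa3+/+).

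Of 324 list tests 134 were called, and 33 with an estimated correlation. The median of the epididymis and testis markers turned or vanished without Cpa3+/+ LFD array 3. For the diet in Cpa3+/+ it was -0.025 without that array or the 4 arrays (-1.30 at lowest with others left out). For KitW/Wv against Cpa3+/+ on LFD it was 0.040 and 0.090 (-0.88 at lowest), and for Cpa3Cre/+ against Cpa3+/+ on LFD 0.11 without either (-0.82 at lowest). Without the 4 arrays, chemokines had -0.13 for the diet in KitW/Wv and muscle markers 0.23 for the interaction of KitW/Wv and Cpa3Cre/+. Of the arrays left out, KitW/Wv HFD array 1 had a mean deviation of 0.68 in chemokines and 2.07 in muscle markers. Cpa3Cre/+ LFD array 2 had 1.09 in muscle markers. The other KitW/Wv HFD arrays had -0.24 and 0.05 in chemokines. Adipocyte markers in Cpa3Cre/+ against Cpa3+/+ on LFD ran from -0.14 to 0.28 (without Cpa3Cre/+ LFD array 2), and endothelial markers in KitW/Wv against Cpa3Cre/+ on LFD from 0.028 (without KitW/Wv LFD array 1) to 0.37.

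The correlation of the diet effects in Cpa3+/+ and Cpa3Cre/+ was 0.747 without background correction, 0.723 without the 4 arrays and 0.594 to 0.682 with each array left out. Without the 4 arrays it was 0.0461 for Cpa3+/+ and KitW/Wv and 0.0313 for Cpa3Cre/+ and KitW/Wv, and with each array left out 0.025 to 0.153 and 0.088 to 0.309. Of 351 named gene results past the threshold, 0 were reversed and 178 passed under every alternative. A block for the array chip was not run, as no chip is named. In the sample numbers most HFD arrays come first and most LFD arrays next, in all genotypes. A batch that followed this order could not be fully separated from the diet within a genotype. The KitW/Wv arrays follow the same order. Over the 798 genes called in Cpa3+/+, taken in the direction of that call, their median change was 0.098 (upper quartile 0.261), against 1.291 in Cpa3Cre/+. For these genes, the values argue against a batch that acts alike on all genotypes as the source of the diet changes.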

Other observations

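The tests of epididymis markers and of the B cell score were chosen after the results were seen.

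Of the lists of lipid and energy metabolism, 1 was called for the diet with an estimated correlation, and single genes moved in others. In Cpa3+/+ the carnitine transferase gene Cpt1b rose by 1.47 (SE 0.28) and the leptin gene Lep by 1.74 (SE 0.43), 1 of 20 fatty acid oxidation genes (list median 0.19, camera adjusted p = 0.021, and 0.606 with an estimated correlation) and 1 of 17 adipocyte markers. In Cpa3Cre/+ Cpt1b rose by 1.59 (SE 0.25) and Acaa1b by 1.27 (SE 0.29, not past the threshold with only the groups compared in the fit), and 3 of 24 oxidative phosphorylation genes fell, with Sdhb at -0.77 (list median -0.33, camera adjusted p = 8.67e-05, and 0.494 with an estimated correlation). Fatty acid synthesis genes had medians of -0.18 in Cpa3+/+ and 0.18 in Cpa3Cre/+ (camera adjusted p = 0.421 and 0.959), and insulin signalling genes -0.17 and -0.13 (camera adjusted p = 0.228 and 0.419). Thermogenic adipocyte genes were higher as a list in Cpa3+/+ (median 0.90, adjusted p = 0.00895 with an estimated correlation), with the proton channel gene Otop1 at 2.97 (SE 0.30). Ucp1, not detected on any LFD array, was at least 2.47-fold higher on HFD (adjusted p = 0.0927) and did not pass. They were lower in KitW/Wv than in Cpa3+/+ on HFD (median -0.80, adjusted p = 0.00939 with an estimated correlation), where Otop1 fell by 3.20 on the log2 scale. The rise was not particular to Cpa3+/+. In Cpa3Cre/+ the mean deviation of the list per array was 0.36 to 0.59 on HFD and -0.54 to 0.11 on LFD. In Cpa3+/+ it was 0.43 to 0.88 and -0.32 to -0.10. Otop1 also responded less in KitW/Wv than in Cpa3Cre/+ (-2.73, limma adjusted p = 0.00125). Of the 12 adipose expansion genes, Mest rose in Cpa3+/+ (2.58, SE 0.46) and in Cpa3Cre/+ (2.33, SE 0.41), and Cyp2e1 fell in both (-0.66 and -1.01). The lists had medians of 0.43 and 0.14 (camera adjusted p = 0.228 and 0.999). In Cpa3+/+ the calls of Lep (1.66 to 1.82) and Cyp2e1 (-0.75 to -0.56) were lost without either HFD array, that of Cpt1b without HFD array 2 (1.32) and that of Mest without HFD array 1 (2.50). Lep lost its call also without LFD array 1 (1.49) or 2 (1.69), Cyp2e1 without LFD array 1 (-0.64) or 3 (-0.61), and Sdhb in Cpa3Cre/+ without HFD array 1 or 2 or LFD array 1 or 3 (-0.79 to -0.68).

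The lists of other cell types held few members past the threshold for the diet. Alternatively activated macrophage markers had a median of 0.20 in Cpa3+/+ (0 of 14 past the limma threshold) and 0.39 in Cpa3Cre/+, where Clec10a (1.01) and Mrc1 (0.87) rose. Clec10a lost its call without Cpa3Cre/+ HFD array 3 (0.79), and Mrc1 without array 1 (0.84) or array 2 (0.89). Interferon response genes had medians of 0.08 and 0.15 (camera adjusted p = 0.883 and 0.419), and endothelial markers 0.33 and 0.14 (camera adjusted p = 0.0496 and 0.789, and 0.612 for the first with an estimated correlation). Stromal progenitor markers had a median of 0.60 in Cpa3+/+ (camera adjusted p = 0.00329, and 0.0707 with an estimated correlation), and mesothelial and epithelial markers -0.90 (camera adjusted p = 0.0112, and 0.361 with an estimated correlation). Among 14 immediate early genes Atf3 rose in Cpa3+/+ (2.61, SE 0.39) and in Cpa3Cre/+ (3.28, SE 0.35), and was lower in KitW/Wv than in Cpa3Cre/+ on HFD (-2.91). In the last comparison red blood cell markers had a median of 1.20 (camera adjusted p = 0.00349, and 0.305 with an estimated correlation), and 6 of their 9 members were highest in KitW/Wv HFD array 3. There Prg2, 1 of 3 measured eosinophil markers, was 1.20 higher (SE 0.32, adjusted p = 0.0345). Its call was lost without Cpa3Cre/+ or KitW/Wv HFD array 2 or 3 (0.94 to 1.21). T and NK cell markers had a median of 0.03 (camera adjusted p = 0.338).

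The higher B cell markers of KitW/Wv may reflect lymph node tissue in 1 sample, blood left in the tissue, or B cells in the fat. Without KitW/Wv HFD array 1 the median difference from Cpa3+/+ on HFD was 0.811, near the limit of 0.752 that is 0.5 of the full 1.504. The margin used was the SD of the members over the root of their number (0.403), which treats the genes as independent. Within that margin the test cannot tell. The difference in the B cell score was 1.40 (SE 0.38) with the red blood cell score as a covariate and 1.23 (SE 0.24) without. This does not exclude blood, because the red blood cell score goes along with the genotype. It was 0.29 to 1.54 in the KitW/Wv arrays other than HFD array 1 (-0.18), and at most 0.18 in the other genotypes. In the B cell score, all 6 KitW/Wv arrays lay above all 11 others, but the list was singled out on these same arrays. Its calls on HFD were lost with an estimated correlation (adjusted p = 0.191 against Cpa3+/+ and 0.305 against Cpa3Cre/+), as was that against Cpa3+/+ on LFD (0.191).

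The epididymis markers of Cpa3+/+ LFD array 3 may come from epididymis tissue in the sample. In that array 6 of 11 markers were at least 4-fold above the median of the other 16 arrays, led by Lcn8 (288-fold) and Adam7 (163-fold). The array was singled out by these same markers, so they do not test the explanation, and it stays open. A sample of another genotype is excluded, since Cpa3 there lay 2.12 above the highest array of the other genotypes and Mcpt4 2.51 above.

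Regrouping 6 arrays into 3 and 3 allows 10 splits, too few for a share under 0.05. As many genes as in the real grouping came from 1 split for the diet in Cpa3Cre/+ (1562, highest other 1), 2 for the diet in KitW/Wv (1, highest other 2), 1 for KitW/Wv against Cpa3+/+ on LFD (8, highest other 0) and 1 for Cpa3Cre/+ against Cpa3+/+ on LFD (6, highest other 1). The values were 1 for KitW/Wv against Cpa3Cre/+ on HFD (1348, highest other 0) and 10 on LFD (0, highest other 3).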
